A study of Mus musculus with 8 samples.

How the data were processed

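Messenger RNA profiles of bone marrow mesenchymal stem cells in osteogenic differentiation were compared between 4 scaffold extract arms on 2 days. The labels name the arms PCL-O, PCL-S, PCL-E and PCL-SE and the series design names a blank, an S7, an E7 and a combined group; PCL-O was taken as the blank by elimination. Per the labels, RNA was extracted with TRIzol and libraries were made with a SMARTER mRNA kit. The extraction protocol gives n = 3 RNA samples, whereas the deposited table has 1 column per arm and day, and whether RNA was pooled is not given in the sources used here.

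The deposited counts are whole numbers per gene and library, per the file headers; the aligner, the counting tool and their versions are not given in the sources used here. The deposited FPKM values were scaled by the authors per kilobase and per fragment total, per the file headers, and were used here only to derive gene lengths. The authors' deposited log2 fold changes and calls come from edgeR at p 0.05 and fold 1.5, per the file headers, which do not give the number of libraries per side. They were compared only with the pair ratios computed here (r = 0.916 across genes for PCL-S against PCL-O on day 7, where the authors called 6526 genes). A further 16 comparison columns carry repeated headers, and these were not used here. Of 26873 features, 22050 have rat Ensembl gene identifiers, 0 have mouse ones and 4823 are new genes without a symbol, although the labels give Mus musculus and mm10. The species was left open, no coordinates were used, and gene symbols follow the rat identifiers. In the table, 10 lines were fragments of annotation text and were left out.

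Counts were filtered with filterByExpr and scaled with TMM in edgeR 4.0.16 (R 4.3.3), which left 15942 genes. Every planned comparison of single arms within a day has 1 library per side and could not be tested; for these, log2 ratios of TMM-normalised CPM with 2 added are given, and list medians are placed among 10000 random lists matched on mean expression. The planned substitute was an additive fit of arm and day with quasi-likelihood F-tests (3 residual degrees of freedom, biological coefficient of variation 0.281). A fit of S7, day, their interaction and E7 (3 residual degrees of freedom, coefficient 0.137) was added after the data were seen. Genes were called at an adjusted p (Benjamini-Hochberg) under 0.05; error is the standard error of the log2 fold change, and CPM are given as mean ± SD. Printed CPM are scaled to library totals without TMM, whereas fold changes and ratios use TMM, so small differences in CPM can depart from them. Fold changes against libraries without a count use a floor of 3 counts per library, scaled with TMM unless stated.

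Genes were named by a rule: the largest rises and falls among called genes with non-overlapping CPM and at least 5 CPM in the higher group, the smallest p where none was called, and for pairs the largest ratios with at least 20 CPM in either library. A gene that this rule names is not reported here. Any member of a fixed gene list and 5 reference genes could be named too; which list members appear was chosen after their values were seen. Of 43 fixed gene lists (870 of 916 genes matched), 41 had enough tested members. They were tested with camera from limma 3.58.1 at its preset correlation, with a correlation estimated per list, and with fry. Gene ontology terms were tested with Fisher's exact test. The rules, these lists and the first set of alternatives were fixed before the data were examined. On counts simulated from these libraries, 23% of 2-fold and 91% of 4-fold changes were recovered for PCL-S against PCL-O, 83% and 98% for S7 on day 3, and 75% and 97% for S7 on day 7.

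The alternatives were DESeq2 1.42.0, DESeq2-style size factors in edgeR, no low-count filter, a 2-fold minimum and leaving out each library; total-count scaling, removal of a gene length trend and omission of the E7 term were added after the data were seen. Tables and figures used Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.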

Results

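Messenger RNA libraries of bone marrow mesenchymal stem cells, 8 in all, were compared, 1 for each of 4 scaffold extracts on day 3 and day 7 of osteogenic differentiation. The number of cultures behind each library is not given in the sources used here. The extracts of polycaprolactone scaffolds are labelled PCL-O, PCL-S, PCL-E and PCL-SE, and the series design names a blank, an S7, an E7 and a combined group. The labels were read as blank (PCL-O, by elimination), S7 (PCL-S), E7 (PCL-E) and S7 with E7 (PCL-SE). The series title calls S7 and E7 peptides, and their sequences and doses are not given in the sources used here. In the text, the arms with S7 are PCL-S and PCL-SE, and the arms without it are PCL-O and PCL-E. Total counts ran from 32950326 in PCL-S day 7 to 41754124 in PCL-E day 7, and 15942 of 26873 features had enough counts to be tested. At this depth, 3 counts correspond to 0.0719 to 0.0911 CPM (counts scaled to the library total, without TMM), and floors and intervals cover counting error only. Because each arm and day has 1 library, a difference between single arms within a day carries no replicate check and no p-value.

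The PCL-S and PCL-SE libraries lay close together on each day and apart from PCL-O and PCL-E. Elastin (Eln), the core protein of elastic fibres, stood at 5.80 CPM in PCL-S and 16.5 in PCL-SE on day 7, against 1011 in PCL-O and 305 in PCL-E. Fkbp5, a co-chaperone gene induced by glucocorticoids, stood at 151 and 151 CPM in PCL-S and PCL-SE on day 3, against 7.48 in PCL-O and 16.4 in PCL-E. Among genes with at least 20 CPM in either library, 9 of 6800 differed 2-fold or more between PCL-SE and PCL-S on day 3, and 19 of 7558 did on day 7. Between PCL-S and PCL-O the numbers were 407 of 7013 on day 3 and 1408 of 7859 on day 7, and between PCL-E and PCL-O they were 24 of 6781 and 133 of 7077. The first principal component held 55.0% of the variance and set PCL-S and PCL-SE on day 7 apart, and the second held 21.8% and set PCL-S and PCL-SE on day 3 apart.

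**Figure D1:**
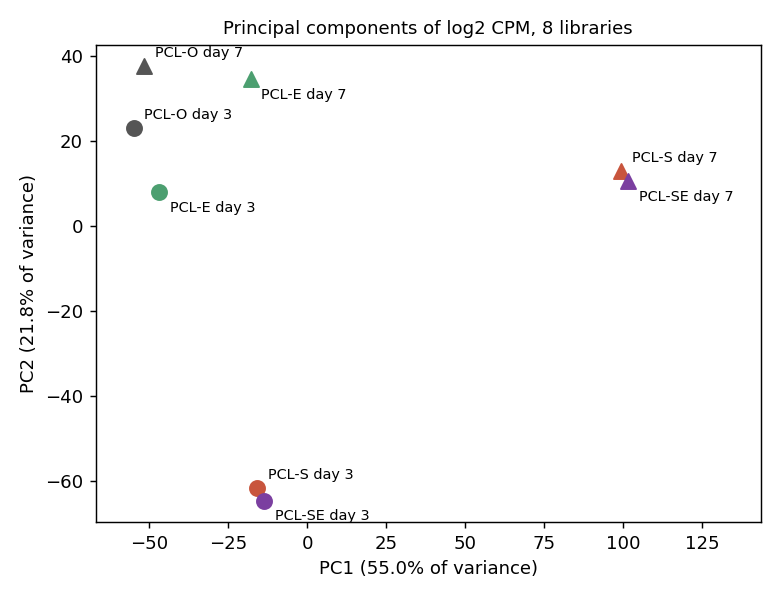
Principal components of log2 CPM over the 15942 tested genes, with 1 point per library (circles day 3, triangles day 7; colours mark the arm). The first axis holds 55.0% of the variance and the second 21.8%; on each day PCL-S and PCL-SE nearly coincide.

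What S7 did to the cells was asked by comparing PCL-S with PCL-O over both days, with day as a block. Xdh, the xanthine dehydrogenase of purine breakdown, rose to 22.5 ± 1.59 CPM from 0.132 ± 0.0586 (mean ± SD, n = 2 libraries each; log2 fold change 7.27 ± 0.42 (SE), adjusted p = 0.0132). Hopx, a homeodomain cofactor, rose to 14.3 ± 3.96 from 0.223 ± 0.0702 CPM (5.84 ± 0.38, adjusted p = 0.0132). Mt2A, a metallothionein that binds zinc and copper, rose to 35.6 ± 32.99 from 0.639 ± 0.0837 CPM (5.31 ± 0.53, adjusted p = 0.0259). Hif3a, a hypoxia-inducible factor subunit, reached 21.1 CPM in PCL-S day 3 and 0.303 on day 7, against 0.0579 and 0 in PCL-O. Myh2, a fast skeletal muscle myosin, was among the genes that fell most (1.61 ± 0.939 from 82.3 ± 34.9 CPM, -5.86 ± 0.34, adjusted p = 0.0132). Scg2, a secretogranin of secretory granules, fell too (-5.84 ± 0.45, adjusted p = 0.0132). Also lower were Adamts8, a secreted metalloproteinase (-4.88 ± 0.35, adjusted p = 0.0132), Tmem200a (-4.78 ± 0.57) and Ighm, an immunoglobulin heavy chain (-4.54 ± 0.56).

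Genes induced by glucocorticoids were the group with the highest median in PCL-S: 6 of 16 tested members rose and 0 fell (10 rose when adjusted over the list alone). Their median log2 fold change was 2.08 (camera adjusted p = 9.1e-09; adjusted p = 0.696 with an estimated correlation). Ribosomal protein genes had a median of 0.71, with 0 of 31 called over all genes and 23 when adjusted over the list alone (camera adjusted p = 3.0e-10; adjusted p = 0.906 with an estimated correlation). Chondrocyte markers had a median of -1.14, with 1 of 14 fallen and 8 when adjusted over the list alone (camera adjusted p = 6.6e-04; adjusted p = 0.906 with an estimated correlation). Among gene ontology terms, growth factor activity was enriched in the genes that fell (6 of 69, Fisher's exact test adjusted p = 0.0347). In all, 82 genes rose and 119 fell by edgeR's quasi-likelihood test; DESeq2 called 1555. Total-count scaling moved the median of all genes by 0.13 here (log2) and by 0.14 for PCL-SE. The spread here is the departure from additive arm and day effects, and leaving out any 1 library lowered the count. It was 94 without PCL-O day 3 (60 of them among the 201), 56 without PCL-SE day 3, 54 without PCL-SE day 7, 4 without PCL-E day 3 or PCL-E day 7, and 1 without PCL-S day 3, PCL-S day 7 or PCL-O day 7.

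With E7 added to S7, PCL-SE was compared with PCL-O in the same way. Gda, the guanine deaminase of purine breakdown, rose to 93.5 ± 11.7 from 2.54 ± 0.462 CPM (mean ± SD, n = 2 libraries each; log2 fold change 5.07 ± 0.15 (SE), adjusted p = 0.00163). Xdh (7.10 ± 0.41, adjusted p = 0.0129) and Hopx (5.62 ± 0.37, adjusted p = 0.0129) rose as well. Hif3a reached 18.9 CPM on day 3 and 0.56 on day 7. Scg2 (-7.04 ± 0.48), Myh2 (-5.45 ± 0.33), and Adamts8 (-5.28 ± 0.35) fell. So did the cartilage collagen gene Col9a2 (7.005 ± 5.46 from 198 ± 22.4 CPM, -5.07 ± 0.62, adjusted p = 0.0319) and the growth factor gene Pdgfb (-5.01 ± 0.73, adjusted p = 0.04996). Of the glucocorticoid response list 6 of 16 members rose (11 adjusted over the list alone; median 1.93, camera adjusted p = 1.2e-08; adjusted p = 0.696 with an estimated correlation). Hippo and YAP targets had a median of -0.72, with 0 members called over all genes and 9 of 15 lower when adjusted over the list alone (camera adjusted p = 2.7e-04; adjusted p = 0.906 with an estimated correlation). In all, 78 genes rose and 118 fell; DESeq2 called 1626. The count was 104 without PCL-O day 3 (66 of them among the 196), 21 without PCL-S day 7, 15 without PCL-S day 3, 4 without PCL-E day 3 or PCL-E day 7, and 1 without PCL-SE day 3, PCL-SE day 7 or PCL-O day 7.

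E7 alone was asked about by comparing PCL-E with PCL-O. No gene passed the test. The smallest p belonged to Gda (7.54 ± 1.96 against 2.54 ± 0.462 CPM, mean ± SD, n = 2 libraries each; adjusted p = 0.463). Next came Xdh (log2 fold change 3.25 ± 0.42 (SE)), Myh2 (-1.70 ± 0.27), and Hopx (2.23 ± 0.37). Gchfr, a regulator of tetrahydrobiopterin synthesis, had no count in PCL-O and was at least 3.89-fold higher against a floor of 3 counts per library. The adjusted p of the last 4 was 1. Interferon-stimulated genes had a median log2 fold change of 0.30 over 21 members (camera adjusted p = 6.9e-05; adjusted p = 0.772 with an estimated correlation). Ribosomal protein genes had one of 0.19 (camera adjusted p = 8.2e-05; adjusted p = 0.906 with an estimated correlation). In either list 0 members were called. The edgeR count was 0, with 228 genes at an unadjusted p under 0.05, and DESeq2 called 7. As for PCL-S, the spread is the departure from additive arm and day effects, so an E7 difference present on 1 day only counts as spread.

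How the cells changed from day 3 to day 7 over all arms was tested with arm as a block, and 6 genes fell while 0 rose. Adamts15, a secreted metalloproteinase, was 1 of the 6 (10.9 ± 7.36 from 51.2 ± 28.2 CPM, mean ± SD, n = 4 libraries each; log2 fold change -2.51 ± 0.17 (SE), adjusted p = 0.047). Cavin2, a caveolar coat gene, was another (2.88 ± 0.843 from 16.8 ± 7.16 CPM; -2.67 ± 0.20, adjusted p = 0.0489). Integrin and focal adhesion genes had a median of -0.54 over 24 members (camera adjusted p = 2.7e-04; adjusted p = 0.906 with an estimated correlation). Oxidative phosphorylation genes had one of 0.25 (camera adjusted p = 0.00128; adjusted p = 0.906 with an estimated correlation), with 0 members of either called. An unadjusted p under 0.05 was reached by 3602 genes, and DESeq2 called 1590. In this additive fit a day change that differs between arms counts as spread. The fit with an interaction of S7 and day, given below, called 256 genes between the days in the arms without S7 and 8090 with S7. Total-count scaling moved the median of all genes by 0.19 and called 4 higher and 6 lower in place of 0 and 6, and without a low-count filter there were 12 and 30. None of the 6 was called with any single library left out. Without PCL-O day 3 or PCL-O day 7, 2 other genes rose, and 0 were called without PCL-S, PCL-E or PCL-SE on day 3 or on day 7.

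Set side by side within day 3, the library pairs PCL-S and PCL-O differed in the following genes. All pair values are log2 ratios of normalised CPM with 2 added, come from 1 library each and carry no test. With 0.5 added, a setting chosen after seeing the data, values of genes near 0 CPM in a library are further from 0, and printed ones that move by 1.5-fold or more are given again below. Gda (4.44), Col7a1, the anchoring fibril collagen (4.19), Fkbp5 (4.04; 151 against 7.48 CPM), Epas1, the hypoxia-inducible factor 2 alpha subunit (3.85; 469 against 31.1 CPM), and Tnn, a tenascin (3.84), were higher in PCL-S. Adamts8 (-5.35), Scg2 (-4.99), Myh2 (-4.71), Col9a2 (-3.84), the insulin-like growth factor binding protein gene Igfbp2 (-3.53; 295 against 3447 CPM) and the growth factor gene Igf1 (-3.20) were lower. PCL-SE against PCL-O on day 3 gave 4.45 for Gda, 4.03 for Fkbp5, 3.82 for Epas1, -5.40 for Adamts8 and -3.52 for Igfbp2. The median log2 ratio of the glucocorticoid response list was 1.51 in PCL-S and 1.36 in PCL-SE, above all 10000 random lists matched on expression (percentile 100). In PCL-E the values were smaller: Epas1 was 1.35 and Crispld2, a glucocorticoid-responsive secreted protein gene, 0.92. Cd248, a stromal surface protein gene, was -1.57, the Wnt receptor gene Fzd8 -1.35 and Myh2 -1.22. Higher and lower by 2-fold or more were 179 and 228 genes in PCL-S, 7 and 17 in PCL-E, and 183 and 217 in PCL-SE. Dr1, Rps27a, Fau, Surf4, Pak2 and Ftl1 stand among the extreme ratios of single pairs, but have near-identical copies between which reads can be split, so their values are uncertain. With 0.5 added, Col7a1 was 4.83 and Scg2 -5.82 in PCL-S.

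On day 7, Akr1b8, an aldo-keto reductase, was 7.56 higher on this log2 scale in PCL-S than in PCL-O (2108 against 7.37 CPM) and 7.41 higher in PCL-SE. Angptl4, a secreted inhibitor of lipoprotein lipase (6.63 and 6.38), the glutaredoxin gene Glrx (5.69 and 5.47) and the glucocorticoid-induced kinase gene Sgk1 (5.15 and 5.07) were higher in both arms. So was the chemokine gene Ccl7 (4.51 and 4.41). Eln (-7.24 and -6.03), Col2a1 (-5.68 and -6.21), Abi3bp (-4.95 and -5.13), the basement membrane gene Hmcn1 (-4.56 and -5.07) and Fras1 (-4.49 and -4.69) were lower. PCL-E on day 7 differed from PCL-O in part of these genes: Cyp1a1, the cytochrome induced through the aryl hydrocarbon receptor, was 4.17 (49.3 against 0.759 CPM), Angptl4 3.67, Akr1b8 3.61, Ccl2 2.33 and Nqo1 2.02. Igfbp3 was -2.67, Eln -1.82 and Fbn2, a fibrillin gene, -1.76. The NRF2 target list had a median of 0.42 in PCL-E (percentile 100 among the random lists), 1.40 in PCL-S and 1.43 in PCL-SE. The fibrillar matrix list had medians of -0.36 in PCL-E and -1.64 in PCL-SE (percentile 0 in each). The glucocorticoid response list had medians of 1.77 and 1.62 in PCL-S and PCL-SE and 0.04 in PCL-E. Higher and lower by 2-fold or more were 612 and 796 genes in PCL-S, 56 and 77 in PCL-E, and 556 and 739 in PCL-SE. Without TMM, a setting chosen after seeing the data, they were 1216 and 522, 67 and 60, and 1147 and 487, so which direction has more genes depends on the scaling. With 0.5 added, Angptl4 was 8.28 in PCL-S, 8.03 in PCL-SE and 5.26 in PCL-E, where PCL-O had 0.182 CPM, and Cyp1a1 was 5.24 in PCL-E. In PCL-S and PCL-SE, Ccl7 was 5.33 and 5.23, Col2a1 -6.36 and -7.34, and Abi3bp -5.96 and -6.36.

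Whether E7 adds to S7 was asked by setting PCL-SE against PCL-S. On day 3, the cell cycle inhibitor gene Cdkn2b (1.33) and the immediate early gene Egr1 (0.73) were higher in PCL-SE and Map2, a microtubule-associated protein gene (-1.04) was lower, and 4 genes were higher and 5 lower by 2-fold or more. On day 7, Ctdspl2 (1.32) and Tnn (1.03) were higher and Ripor2 (-1.88), Igfbp2 (-1.18) and the chemokine gene Cxcl1 (-0.96) lower, with 12 and 7 genes past 2-fold. PCL-SE against PCL-E, which asks about S7 in the presence of E7, gave 3.28 for Gda, 3.09 for Fkbp5 and -5.48 for Scg2 on day 3 (123 genes higher and 139 lower). On day 7 it gave 4.61 for Glrx, 4.48 for Sgk1 and -4.78 for Col2a1 (304 and 467; 531 and 354 without TMM). PCL-E against PCL-S gave 5.28 for Scg2 and -3.91 for Col7a1 on day 3 (140 and 125), and 5.42 for Eln and -4.82 for Glrx on day 7 (495 and 324; 363 and 550 without TMM). The departure of PCL-SE from the sum of the S7 and E7 ratios was 1 log2 unit or more for 18 genes above and 14 below on day 3, with Fos at 1.51 and Epas1 at -1.38. On day 7 it was that large for 101 genes above and 110 below, with Eln at 3.03 and Igfbp3 at 2.47, and Cyp1a1 at -4.26, Angptl4 at -3.92 and Akr1b8 at -3.76. With 0.5 added, Scg2 was -6.49 in PCL-SE against PCL-E and 6.12 in PCL-E against PCL-S on day 3, and Col2a1 was -5.89 in PCL-SE against PCL-E on day 7. The day 7 departures were then -5.51 for Angptl4 and -5.34 for Cyp1a1.

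From day 3 to day 7 within single arms, PCL-O had higher values of the matrix genes Fndc1 (2.46) and Lum (1.91) and of Enpp1, which makes pyrophosphate (1.91). It had lower Cyp26b1, which degrades retinoic acid (-3.30), Scg2 (-2.06), Id2 (-2.03) and the BMP antagonist gene Nog (-1.98), with 52 genes higher and 84 lower by 2-fold or more. In PCL-E, Angptl4 (3.11), Cyp1a1 (3.00), Ccl2 (2.96) and Lum (2.67) were higher and Lama5, a laminin gene (-3.51), and Eln (-2.40) lower (59 and 95 genes). In PCL-S, Angptl4 (6.35), Akr1b8 (4.98) and the haem oxygenase gene Hmox1 (4.13) were higher. Eln (-6.75), Lama5 (-5.06), Casq2, a calcium store protein gene (-4.85), Actg2 (-4.76) and the smooth muscle myosin gene Myh11 (-4.48) were lower (411 and 675; 1042 and 408 without TMM). In PCL-SE the same comparison gave 6.30 for Angptl4, 3.89 for Hmox1 and -5.38 for Eln (357 and 613; 912 and 389 without TMM). The arm's log2 ratio to PCL-O differed between the days by 1 or more for 472 genes upwards and 739 downwards in PCL-S (Hmox1 4.59, Cpt1a 4.24, Tnn -4.90). It did so for 395 and 698 in PCL-SE (Hmox1 4.35, Cd24 4.24, Igfbp4 -4.61), and 74 and 85 in PCL-E (Cyp1a1 4.49, Atoh8 2.45, Igfbp3 -2.36). Without TMM these were 1050 and 487 in PCL-S, 942 and 460 in PCL-SE, and 83 and 65 in PCL-E. With 0.5 added, Angptl4 from day 3 to day 7 was 3.92 in PCL-E, 7.54 in PCL-S and 7.80 in PCL-SE, and Lama5 was -5.73 in PCL-S. The differences between days were 5.10 for Cd24 in PCL-SE and 5.64 for Cyp1a1 in PCL-E.

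Because PCL-S and PCL-SE lay so close together, their shared difference from PCL-O and PCL-E was tested on each day in a fit with S7, day, their interaction and E7. The grouping follows the labels, but this fit was chosen after seeing the data. Each group of n = 2 libraries pools 2 different arms and holds no repeat of an arm. The spread is the departure from the fitted terms. The p-values of this fit therefore rest on how alike the pooled arms are, and not on variation between cultures. On day 3, genes of mitosis were higher in the arms with S7: 27 of 28 tested G2/M members rose and 0 fell. Their median log2 fold change was 0.69 (camera adjusted p = 2.1e-13; adjusted p = 0.519 with an estimated correlation). Top2a, the topoisomerase of dividing cells, rose to 143 ± 2.93 from 89.04 ± 8.90 CPM (mean ± SD, n = 2 libraries each; 0.70 ± 0.11 (SE), adjusted p = 0.00968). The proliferation marker Mki67 rose to 175 ± 0.25 from 95.3 ± 11.7 CPM (0.89 ± 0.17, adjusted p = 0.0163). Of the G1/S and S phase list 14 of 31 rose and 0 fell (median 0.51, camera adjusted p = 1.4e-08; adjusted p = 0.519 with an estimated correlation), 20 when adjusted over the list alone. Genes induced by glucocorticoids rose together: 11 of 16 rose and 0 fell, 13 when adjusted over the list alone (median 1.40, camera adjusted p = 2.0e-08; adjusted p = 0.519 with an estimated correlation). Among them were Fkbp5 (151 ± 0.131 from 11.9 ± 6.29 CPM; 3.74 ± 0.26, adjusted p = 0.00121) and the transcription factor gene Zbtb16 (3.62 ± 0.20, adjusted p = 7.3e-04). Others were Sgk1 (2.37 ± 0.18), the glutamine synthetase gene Glul (1.96 ± 0.15), Tsc22d3, which encodes the glucocorticoid-induced leucine zipper (1.37 ± 0.11), and Klf9 (0.98 ± 0.08).

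Among the largest rises on day 3 by the naming rule were the heparan sulfate sulfotransferase gene Hs3st1 (5.91 ± 0.658 from 0.0865 ± 0.0814 CPM) and Hif3a (20.01 ± 1.55 from 0.389 ± 0.468). They were followed by Xdh (24.3 ± 0.987 from 0.678 ± 0.713) and Timp4, a metalloproteinase inhibitor gene (5.60 ± 0.494 from 0.173 ± 0.0811). The largest falls were Scg2 (1.07 ± 0.274 from 110.3 ± 17.8 CPM), Adamts8 (14.9 ± 0.275 from 533 ± 231), Myh2, Ighm and Pclo. Cholesterol synthesis genes rose in 7 of 23 cases (camera adjusted p = 5.1e-05; adjusted p = 0.587 with an estimated correlation). Ribosomal protein genes rose in 12 of 31 (camera adjusted p = 6.9e-08; adjusted p = 0.532 with an estimated correlation), with 0 falls in either. Tendon and smooth muscle or myofibroblast markers fell in 7 of 14 cases and rose in 0 (camera adjusted p = 0.00388; adjusted p = 0.519 with an estimated correlation). Among them were the smooth muscle actin gene Acta2 (-0.59 ± 0.10, adjusted p = 0.0133) and Tagln (-0.48 ± 0.10, adjusted p = 0.0214). Chondrocyte markers fell in 5 of 14 and rose in 2 (camera adjusted p = 0.0189; adjusted p = 0.519 with an estimated correlation). Col2a1, the main cartilage collagen, stood at 32.5 ± 7.47 against 210.0 ± 104 CPM (-2.49 ± 0.43, adjusted p = 0.0128). Fibrillar matrix genes went in opposite ways, 8 of 29 rising and 6 falling. Col6a1, a microfibrillar collagen, rose (2887 ± 135 from 703 ± 124 CPM; 2.05 ± 0.16, adjusted p = 0.00131). Periostin (Postn) fell (-1.21 ± 0.19, adjusted p = 0.00937), while Col1a1 did not pass (0.67 ± 0.20, adjusted p = 0.0666). Runx2, the master regulator of osteoblasts, rose (29.7 ± 2.68 from 16.7 ± 2.47 CPM; 0.86 ± 0.13, adjusted p = 0.00873), and Igf1 fell (-3.45 ± 0.46, adjusted p = 0.00577). In all, 1132 genes rose and 1095 fell, 388 and 486 of them by 2-fold or more. With total-count scaling 1023 rose and 1186 fell, so here too the balance depends on the scaling. The count was 257 without PCL-S day 3, 355 without PCL-O day 3, 601 without PCL-SE day 3, 713 without PCL-E day 3, 3847 without PCL-O day 7 and 3825 without PCL-E day 7.

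**Figure D2:**
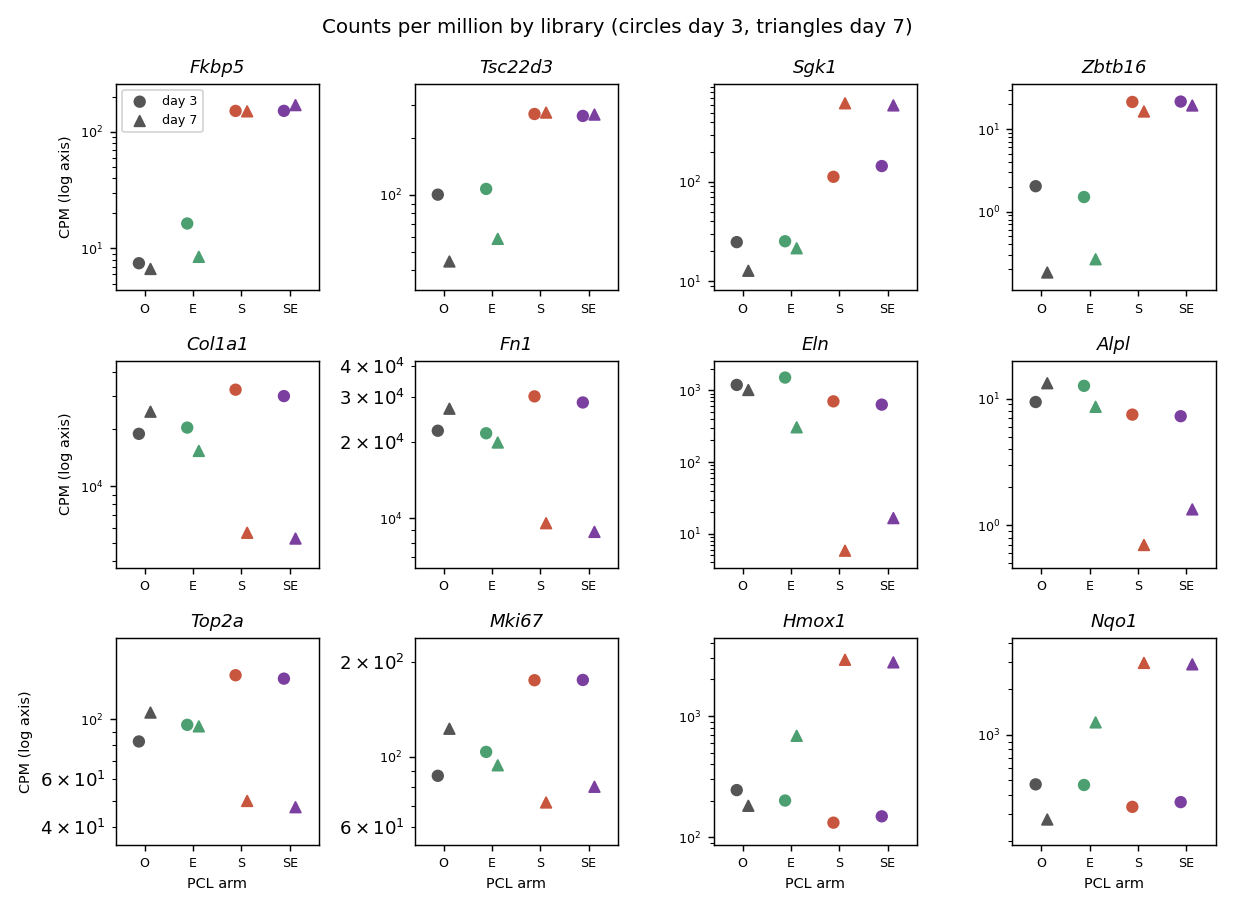
CPM on a log axis for 12 genes in each of the 8 libraries (x axis: PCL arm; circles day 3, triangles day 7; 1 library per point, so no error bars). Fkbp5, Tsc22d3, Sgk1 and Zbtb16 are higher in PCL-S and PCL-SE on both days, Col1a1, Fn1, Eln and Alpl are lower there on day 7, Top2a and Mki67 are higher there on day 3 and lower on day 7, and Hmox1 and Nqo1 are higher there on day 7.

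On day 7, matrix genes were lower in the arms with S7 than in the arms without it. Of the fibrillar matrix list 26 of 29 tested members fell and 0 rose (27 fell when adjusted over the list alone). The median log2 fold change was -1.57 (camera adjusted p = 2.5e-08; adjusted p = 0.519 with an estimated correlation). Col1a1, the main collagen of bone, fell to 5466 ± 273 from 20053 ± 6655 CPM (mean ± SD, n = 2 libraries each; -2.08 ± 0.20 (SE), adjusted p = 4.3e-04). Fibronectin (Fn1, -1.57 ± 0.14, adjusted p = 2.9e-04) and Postn (-2.97 ± 0.20) fell, and Eln fell to 11.2 ± 7.57 from 658 ± 499 CPM (adjusted p = 0.00113). Osteoblast and bone matrix markers fell in 19 of 26 cases and rose in 5 (median -1.23, camera adjusted p = 6.9e-04; adjusted p = 0.519 with an estimated correlation). Alpl, the alkaline phosphatase of mineralising cells, fell to 1.02 ± 0.449 from 10.9 ± 3.25 CPM (-3.64 ± 0.38, adjusted p = 5.2e-04). Sparc, which encodes osteonectin, fell (-1.44 ± 0.09, adjusted p = 1.3e-04). Osteopontin (Spp1) rose by 0.70 ± 0.24 (adjusted p = 0.0485), a rise that rested mostly on PCL-SE. It stood at 2795 CPM in PCL-SE and 1680 in PCL-S, against 1296 in PCL-O and 1022 in PCL-E. The bone morphogen gene Bmp2 rose by 2.33 ± 0.25 (adjusted p = 5.9e-04). The osteoblast transcription factor list went both ways, with 3 of 14 rising and 3 falling (camera adjusted p = 0.856), and Runx2 did not pass (0.36 ± 0.13, adjusted p = 0.0541). Tendon and smooth muscle or myofibroblast markers fell in 11 of 14 cases and rose in 1 (camera adjusted p = 1.8e-04, and adjusted p = 0.519 with an estimated correlation), with Acta2 at -2.19 ± 0.11 and Myh11 at -3.66 ± 0.35. Integrin and focal adhesion genes fell in 19 of 24 with 3 rises (camera adjusted p = 3.5e-04; adjusted p = 0.519 with an estimated correlation).

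Mitotic genes, higher on day 3, were lower on day 7: 22 of 28 G2/M members fell and 0 rose (median -0.66, camera adjusted p = 1.7e-06; adjusted p = 0.519 with an estimated correlation). Top2a was among them (-1.27 ± 0.11 (SE), adjusted p = 3.2e-04). NRF2 targets, the genes of the response to oxidants, rose in 22 of 26 cases and fell in 2 (median 1.38, camera adjusted p = 7.5e-07; adjusted p = 0.519 with an estimated correlation). Hmox1 rose to 2837 ± 99.2 from 434 ± 357 CPM (mean ± SD, n = 2 libraries each; 2.62 ± 0.49, adjusted p = 0.00471). The quinone reductase gene Nqo1 rose to 2936 ± 45.4 from 739 ± 656 (1.95 ± 0.50, adjusted p = 0.0169). The ferritin heavy chain gene Fth1 rose to 6293 ± 798 from 765 ± 448 (2.90 ± 0.32, adjusted p = 6.8e-04) and Gclc, which limits glutathione synthesis, by 1.69 ± 0.12 (adjusted p = 1.9e-04). In PCL-E day 7, Hmox1 stood at 687 and Nqo1 at 1203 CPM, against 182 and 275 in PCL-O. Glucocorticoid-induced genes stayed higher, with 14 of 16 rising and 0 falling (median 2.30, camera adjusted p = 3.6e-06; adjusted p = 0.519 with an estimated correlation). Fkbp5 rose by 4.18 ± 0.26 (adjusted p = 1.4e-04), Sgk1 by 4.96 ± 0.20 (adjusted p = 7.6e-05) and Tsc22d3 by 2.17 ± 0.11 (adjusted p = 9.2e-05). Ribosomal protein genes rose in 26 of 31 cases and nuclear genes of oxidative phosphorylation in 26 of 28, with 0 falls in either. Their camera adjusted p were 1.4e-08 and 2.0e-08 (0.522 and 0.519 with an estimated correlation). The mean gene length weighted by counts was 3135 bp in PCL-S and 3177 bp in PCL-SE on day 7, against 3952 in PCL-O and 3565 in PCL-E. With the length trend removed, a setting chosen after seeing the data, the list medians went from 0.81 to 0.48 and from 0.64 to 0.39, and 24 and 19 members rose. The fat cell regulator Pparg rose to 9.64 ± 3.23 from 0.945 ± 0.865 CPM (3.17 ± 0.56, adjusted p = 0.00379). Cebpb rose by 2.22 ± 0.21 (adjusted p = 4.1e-04) and the lipid droplet gene Plin2 by 1.78 ± 0.24 (adjusted p = 0.00123). Of the adipocyte list 9 of 18 rose and 4 fell, and the list test did not pass (camera adjusted p = 0.112).

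The largest rises on day 7 by the naming rule were Akr1b7, an aldo-keto reductase (at least 141-fold with TMM and 166-fold without it, against a floor of 3 counts per library), and Itprip (7.75 ± 0.246 from 0.0631 ± 0.0463 CPM). Next were Zbtb16 (17.8 ± 2.11 from 0.223 ± 0.0575) and the muscle ring finger gene Trim54 (8.51 ± 1.47 from 0.124 ± 0.0395). Glrx rose as well (432 ± 43.4 from 9.08 ± 4.94; log2 fold change 5.43 ± 0.32 (SE), adjusted p = 1.3e-04; mean ± SD, n = 2 libraries each). The largest falls were Myh3, an embryonic myosin (at least 139.6-fold with TMM and 117-fold without it, no count in PCL-S or PCL-SE), Dr1, which has near-identical copies and is uncertain, and the cadherin gene Cdh8 (0.091 ± 0.129 from 11.5 ± 8.34 CPM). Col2a1 (1.55 ± 0.985 from 133 ± 82.8) came next, and then the muscle gene Smpx (0.0533 ± 0.0754 from 5.12 ± 2.84). Of the reference genes, Actb fell (-0.73 ± 0.09, adjusted p = 9.7e-04), Gapdh, uncertain because of its many copies, rose (0.55 ± 0.09, adjusted p = 0.00245), and B2m fell (-0.73 ± 0.09, adjusted p = 9.4e-04). Hprt1 (0.11 ± 0.13, adjusted p = 0.518) and Tbp (0.23 ± 0.11, adjusted p = 0.13) did not pass. Gene ontology terms enriched among the genes that rose included structural constituents of the ribosome (188 of 287 genes, Fisher's exact test adjusted p = 2.2e-38) and mRNA splicing via the spliceosome (58 of 108, adjusted p = 2.3e-06). Among those that fell they included calcium ion binding (216 of 422, adjusted p = 1.2e-26) and cell adhesion (87 of 148, adjusted p = 1.1e-14). The terms were tested without a correction for gene length, with which the day 7 fold changes correlated at -0.292. Genes with near-identical copies, between which reads can be split, were counted separately in the terms. In all, 3965 genes rose and 4172 fell, 949 and 2115 of them by 2-fold or more. Total-count scaling moved the median of all genes by 0.22 (log2) and the split to 5642 higher and 3010 lower, so small differences have no certain sign. The count was 5003 without PCL-S day 7.

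**Figure D3:**
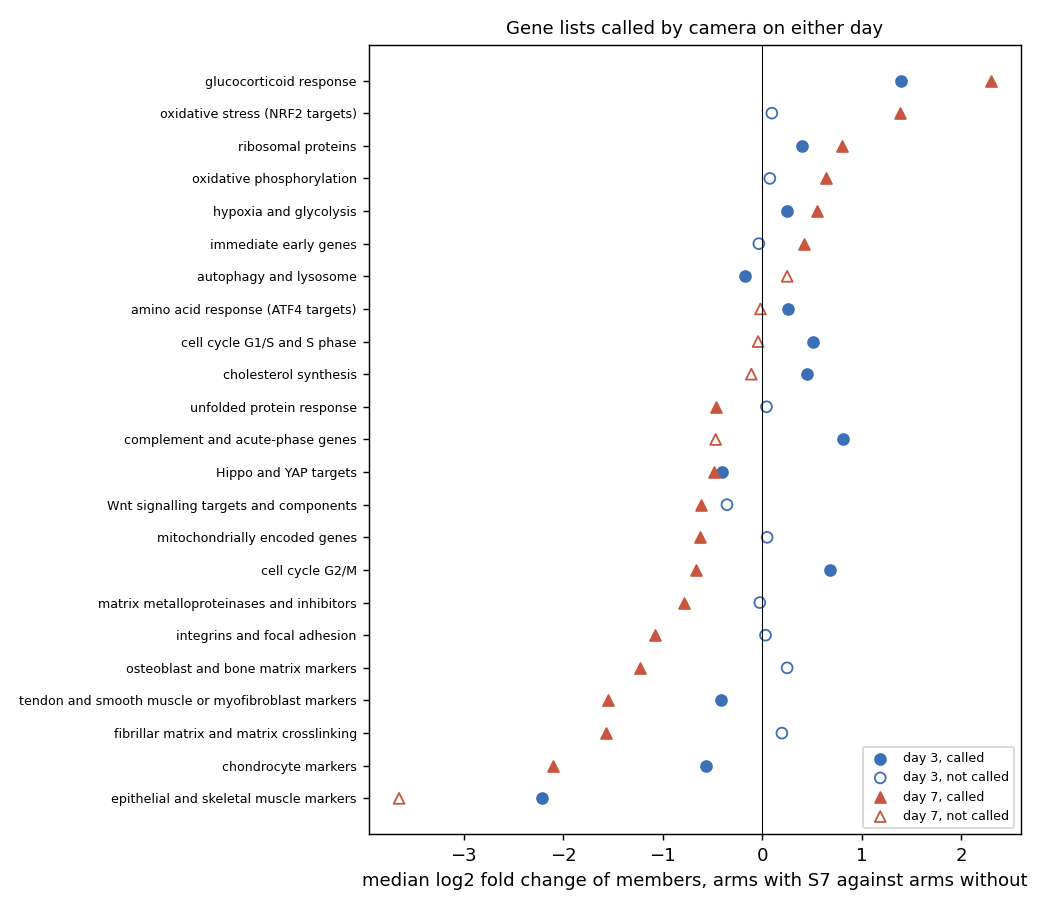
Median log2 fold change of the members of each gene list in the arms with S7 against the arms without it, on day 3 (circles) and day 7 (triangles), for the 23 lists called by camera on either day; filled points were called on that day and open ones were not. The G2/M list lies at 0.69 on day 3 and -0.66 on day 7, and the fibrillar matrix list at 0.20 and -1.57. Calls are by camera at its preset correlation, and with an estimated correlation 0 lists were called on either day.

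Whether the difference itself changed between the days was tested with the interaction term. The G2/M list changed downwards in 27 of 28 members (median -1.39, camera adjusted p = 3.4e-13; adjusted p = 0.519 with an estimated correlation). The fibrillar matrix list did so in 27 of 29 (median -1.97, camera adjusted p = 2.3e-11; adjusted p = 0.519 with an estimated correlation), with 0 upwards in either. NRF2 targets changed upwards in 19 of 26 and downwards in 2 (camera adjusted p = 2.9e-06; adjusted p = 0.519 with an estimated correlation). The glucocorticoid response list moved by 0.47 in the median and its test did not pass (camera adjusted p = 0.211), with 5 of 16 members changing upwards and 3 downwards. In all, 2105 genes changed upwards and 2473 downwards (3721 and 1750 with total-count scaling, which moved the median of all genes by 0.24). Of the genes called on each day, 500 rose on both days and 780 fell on both, against 281.5 and 286.6 for independent lists. In opposite directions, 231 rose on day 3 and fell on day 7 and 79 did the reverse, both fewer than independent lists would give. The count was 1537 without PCL-SE day 3, 1743 without PCL-O day 3, 1862 without PCL-S day 3, 2244 without PCL-E day 3 and 2278 without PCL-S day 7.

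E7 over both days was asked about in the same fit, with PCL-E and PCL-SE against PCL-O and PCL-S. The smallest p belonged to RT1-CE3, a class I histocompatibility gene of a family with near-identical copies and so uncertain (-1.28 ± 0.24 (SE)). Next was Ttc9 (18.4 ± 14.2 against 24.2 ± 17.8 CPM, mean ± SD, n = 4 libraries each; -0.46 ± 0.09), followed by the kinase-dead ephrin receptor gene Ephb6 (-0.47 ± 0.10) and Gas2 (-0.72 ± 0.16). Grik1 had no count in the libraries with E7, but PCL-S had 0 and 0.091 CPM on days 3 and 7, so the difference rests on PCL-O alone (0.608 and 0.759 CPM). Each had an adjusted p of 0.895. Interferon-stimulated genes had a median of 0.15 (camera adjusted p = 8.7e-05; adjusted p = 0.519 with an estimated correlation). NRF2 targets had one of 0.13 (camera adjusted p = 4.4e-04; adjusted p = 0.539 with an estimated correlation), with 0 members called. The edgeR count was 0, with 589 genes at an unadjusted p under 0.05, and DESeq2 called 1. On simulated counts, 95% of genes changed 2-fold were recovered in this comparison, with an E7 change that was the same on both days and with or without S7. In the data, 133 genes were past 2-fold between PCL-E and PCL-O on day 7, against 24 on day 3. Between PCL-SE and PCL-S on day 7 there were 19. This fit counts such unequal changes as spread, so the 0 calls do not show that E7 changed no gene 2-fold.

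The course from day 3 to day 7 was then tested separately in the arms without and with S7. In the arms without S7, the matrix proteoglycan gene Lum rose to 61.6 ± 23.4 from 10.1 ± 0.366 CPM (mean ± SD, n = 2 libraries each; log2 fold change 2.52 ± 0.31 (SE), adjusted p = 0.0186). Nmu (2.50 ± 0.20), Lrrc15 (2.42 ± 0.35) and Wnt2 (2.21 ± 0.27) rose as well, as did the complement gene C2 (2.03 ± 0.30), Enpp1 (1.85 ± 0.24, adjusted p = 0.0204) and Tnc, a tenascin (1.16 ± 0.15, adjusted p = 0.0206). Bcam (-3.34 ± 0.52), Lama5 (-3.32 ± 0.41), Cyp26b1 (-2.99 ± 0.45), Scg2 (-2.50 ± 0.27), the skeletal actin gene Acta1 (-2.34 ± 0.28) and Zbtb16 (-3.01 ± 0.29, adjusted p = 0.0136) fell. Glucocorticoid response genes fell in 4 of 16 cases and rose in 0 (median -0.57, camera adjusted p = 2.3e-04; adjusted p = 0.519 with an estimated correlation). Immediate early genes had a median of -0.58, with 0 called over all genes and 13 of 24 lower when adjusted over the list alone (camera adjusted p = 5.2e-07; adjusted p = 0.519 with an estimated correlation). In all, 107 genes rose and 149 fell (141 and 138 with total-count scaling, so which direction has more genes depends on the scaling), and DESeq2 called 827. The count was 0 without PCL-O day 3 or PCL-E day 3, 58 without PCL-S day 7, 63 without PCL-SE day 7, 73 without PCL-S day 3 or PCL-SE day 3, 607 without PCL-E day 7 and 1347 without PCL-O day 7.

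In the arms with S7, the phospholipase gene Pla2g7 rose to 85.1 ± 9.34 from 1.72 ± 0.152 CPM (mean ± SD, n = 2 libraries each; log2 fold change 5.30 ± 0.14 (SE), adjusted p = 2.7e-05). Angptl4 rose to 228 ± 27.1 from 0.452 ± 0.224 (adjusted p = 0.00396). Cyp1a1 rose to 32.96 ± 1.51 from 0.151 ± 0.131 (adjusted p = 0.015), Akr1b8 by 4.95 ± 0.96 and Akr1b7 to 13.5 ± 0.109 from 0.0244 ± 0.0345 CPM. Eln (-6.18 ± 0.78, adjusted p = 9.8e-04), Lama5 (-6.08 ± 0.45), Hif3a (-5.90 ± 0.63) and Casq2 (-5.88 ± 0.38) fell, with Dr1 uncertain as above. The fibrillar matrix list fell in 27 of 29 cases and rose in 0 (median -1.50, camera adjusted p = 1.1e-08; adjusted p = 0.519 with an estimated correlation). The G2/M list fell in 26 of 28 with 0 rises (median -1.16, camera adjusted p = 2.2e-09; adjusted p = 0.519 with an estimated correlation). Autophagy and lysosome genes rose in 17 of 28 and fell in 3 (camera adjusted p = 7.3e-04; adjusted p = 0.519 with an estimated correlation). In all, 3889 genes rose and 4201 fell. Total-count scaling moved the median of all genes by 0.30 (log2) and gave 6255 higher and 2685 lower. The count was 4479 without PCL-SE day 3, 5009 without PCL-S day 3 and 5193 without PCL-S day 7.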

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

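The test of mixing, the S7 fit with its interaction and the second glucocorticoid list were chosen after results were seen; that list was written before the values of its members were looked at. The difference between arms with and without S7 changed from day 3 to day 7 in 4578 genes by the interaction test, and 310 of these were called on both days in opposite directions (231 higher then lower, 79 lower then higher). Both of these counts are fewer than independent lists of these sizes would give. In the same direction, 500 genes rose and 780 fell on both days, so calls made on both days mostly agreed. Of the fibrillar matrix list 27 of 29 members changed downwards and 0 upwards, and of the osteoblast and bone matrix list 15 of 26 downwards and 2 upwards (camera adjusted p = 5.1e-05; adjusted p = 0.519 with an estimated correlation). Downwards went Alpl by -3.09 (log2, adjusted p = 0.00649), Tnc by -2.85 (0.00127), Vdr, the vitamin D receptor gene, by -2.85 (0.00203), Col1a1 by -2.76 (0.00206), Col6a1 by -2.57 (0.00156), Col3a1 by -2.23 (0.00148), the cathepsin gene Ctsk by -2.05 (8.2e-04) and Fn1 by -2.01 (0.00186). The mitotic genes Kif23 (-1.98, adjusted p = 9.4e-04) and Top2a (-1.97, 0.00136) did so too. Upwards went Hmox1 by 3.30 (adjusted p = 0.0134), Sgk1 by 2.59 (0.00194), Zbtb16 by 2.44 (0.00446), Bmp2 by 2.34 (0.00504), Fth1 by 2.19 (0.0121) and Gclc by 1.43 (0.00284). Zbtb16 did not rise with time in the arms with S7 (21.4 ± 0.159 CPM on day 3 and 17.8 ± 2.11 on day 7). Its change came from the arms without S7, which fell to 0.223 ± 0.0575 from 1.76 ± 0.375 CPM, with 17 counts on day 7.

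For the separation of PCL-S and PCL-SE on day 7, removing the gene length trend left 97.75% of the 3064 genes called at 2-fold or more with their call and direction, while the correlation of fold change with length went from -0.292 to -0.0154. Leaving out the 50 most abundant genes left 99.47% of 3034. Marker lists of blood, endothelial, and epithelial or skeletal muscle cells had a highest median of 0.1821 CPM in the arms with S7, and their most abundant genes, Eng and Cd14, stood at 61.0 and 18.9 CPM in PCL-S. Cd14 was higher with S7 on day 7 (18.4 ± 0.739 from 8.73 ± 0.458 CPM, log2 fold change 0.85 ± 0.12, edgeR adjusted p = 0.0015). Of 20 macrophage and monocyte markers, only 1, Cd14, reached 1 CPM in PCL-S. A list median would miss a small share of added cells, so such a share stays open. These markers speak only to cells added there. The muscle actin gene Acta1 stood at 41.3 CPM in PCL-O and 19.7 in PCL-E, against 2.55 in PCL-S and 0.987 in PCL-SE. A loss of muscle-like cells with S7 was not tested and stays open. A second list of 18 glucocorticoid-induced genes, none from the first, was tested with camera, which gave 0.01047 on day 7 and 0.005746 on day 3 before adjustment, with median log2 fold changes of 0.91 and 0.82; its adjusted p was 0.0628 on both days, and adjusted p = 0.796 with an estimated correlation. Of its members, 11 rose and 2 fell on day 7. Hif3a, Timp4 and Crispld2 are members that the naming rule also names, and on day 7 Hif3a and Timp4 stood at only 0.303 and 1.24 CPM in PCL-S. Without these 3, a setting chosen after seeing the data, camera gave 0.04951 on day 7 and 0.1091 on day 3 before adjustment, with medians of 0.55 and 0.47, and 8 members rose and 2 fell on day 7. By the unadjusted day 7 values a difference in glucocorticoid exposure between the arms may be part of the pattern. Part of the list difference rests on these 3 genes, which were named for large differences in these same libraries. A weaker result without them was therefore likely from the start and cannot decide. The adjustment ran over this list and the reference genes in all comparisons of the S7 fit. With it the list missed the threshold, so a difference in exposure stays open. An action of S7 itself stays open too, since each arm and day has 1 library.

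PCL-E on day 7 lay between PCL-O and the arms with S7. If RNA or reads from an arm with S7 had been mixed in, genes higher and lower there would give the same share; the shares were 0.157 for 166 higher genes and 0.457 for 178 lower genes, a difference of 0.2999 (bootstrap interval 0.25 to 0.347). Mixing alone is unlikely by this test, and no biological explanation was tested.

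Of the 32 splits of the 8 libraries that could be fitted with the arms as a block, 3 called at least as many genes as the 6 of day 7 against day 3, and the highest other called 6624. The splits that called more part the days in PCL-S and PCL-SE only, and put PCL-O whole on one side and PCL-E whole on the other. With the arms as a block they are the same contrast and carry the structure of the samples, so this count does not settle whether the 6 genes arise by chance.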

How the results depend on the processing

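No paired analysis was possible because each arm and day has 1 library and no replicate numbers join them; day and arm entered the fits as factors of the design. The planned replicate block, and the planned restriction to the libraries compared, belong to within-day tests that could not be fitted and were not run. DESeq2 called 1555 genes for PCL-S against PCL-O (201 by edgeR), 1626 for PCL-SE (196), 7 for PCL-E (0), 1590 for day over all arms (6), 1 for E7 over both days (0) and 827 for day in the arms without S7 (256). Without a low-count filter day over all arms gave 42 (12 higher and 30 lower), and with total-count scaling, chosen after seeing the data, 10. A 2-fold minimum left 874 genes for S7 on day 3, 3064 on day 7, 2004 for the difference between days, and 142 and 3083 for day in the arms without and with S7. With 1 library left out the counts ranged from 1 to 94 for PCL-S against PCL-O, 1 to 104 for PCL-SE, 0 to 2 for day over all arms, 257 to 3847 for S7 on day 3, 5003 to 8326 on day 7, 1537 to 6219 for the difference between days, 0 to 1347 for day in the arms without S7 and 4479 to 9206 with S7. An arm left with 1 library is then assumed to vary like the others. PCL-E against PCL-O and E7 over both days stayed at 0 calls by edgeR with any library left out. Size factors of the DESeq2 kind, removal of the length trend and, where tried, omission of the E7 term moved no count by over 1.5 times, and the totals of genes past 2-fold in pairs, higher and lower together, stayed within 1.5 times without TMM or with 0.5 added, settings chosen after seeing the data. Without TMM the balance of higher and lower genes reversed for PCL-S, PCL-E and PCL-SE against PCL-O on day 7, and in other pairs given in the report. Of the gene list tests, camera called 42 in the additive fit, 0 with an estimated correlation and 3 by fry; in the S7 fit it called 84, 0 with an estimated correlation and 109 by fry. For named genes, leaving out 1 library gave the same call 1252 times, ended it 298 times and added it 26 times. The other settings gave 1135, 10 and 13, where the 1135 also hold unmoved pair values of PCL-SE between the days. Of the values of all other pairs, 276 stayed and 162 moved beyond their counting interval, and 12 moved for PCL-SE between the days. Printed ones that moved by 1.5-fold or more are given in the report. No named gene reversed direction. Except where fewer libraries or a stricter threshold account for it, the cause was not tested. At this depth genes under about 0.0719 to 0.0911 CPM rest on fewer than 3 counts.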

Other observations

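Most mitochondrially encoded genes were lower in the arms with S7 on day 7: 10 of 13 fell and 0 rose (median log2 fold change -0.62, camera adjusted p = 0.00851; adjusted p = 0.649 with an estimated correlation), while 26 of 28 nuclear genes of oxidative phosphorylation rose. Mt-nd5, a complex I subunit gene, fell to 1159 ± 46.6 from 2062 ± 128 CPM (mean ± SD, n = 2 libraries each; -1.05 ± 0.08, adjusted p = 2.4e-04). The share of counts from mitochondrial genes as a whole was 3.505% in PCL-S and 3.415% in PCL-SE, between the 3.087% of PCL-O and the 3.848% of PCL-E. Mt-co1 stood at 17300 and 17780 CPM, against 12520 and 15790. The list median was -0.40 with total-count scaling and -0.87 with the length trend removed, settings chosen after seeing the data. Of the 2192 tested new genes without a symbol, 128 rose and 689 fell in that comparison.

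The count of splits for E7 was chosen after the result was seen. All 32 splits of the 8 libraries that could be fitted called at least the 0 genes of the E7 grouping, and the highest other called 2. With 0 genes called, any split reaches that number, so the count says nothing about chance for E7.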
